A study of Mus musculus with 12 samples.

How the data were processed

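RNA was measured in 12 libraries of mouse bone-marrow-derived cells, 3 in each of 4 groups, which were assigned from the sample titles. Per the labels' protocols, marrow cells were grown for 5 days in alpha MEM with 10% FBS, replated, and treated for 2 days with 2% M-CSF alone or with 50 ng/ml RANKL added, and total RNA was extracted with a Qiagen kit and DNase. The deposited values were raw read counts per Ensembl gene, 1 file per library. Per the submitters' processing notes, reads were aligned with STAR 2.0.4b to GRCm38. Counts were made by the authors with featureCounts v1.4.5-p1 on the genes of Ensembl release 76 without use of strand, per the file headers, so reads of antisense or overlapping genes cannot be told apart. Read length and trimming were not given in the sources used here. Files held 41388 genes, of which 40254 had a symbol in GENCODE M21, and 8 symbols carried by a second identifier were kept under that identifier. Coordinates are those of the deposited files.

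Totals of 18489873 to 21667237 counts per library set the precision, and the spread between libraries of a group was small (root of the common dispersion 2.54%). No pair of libraries held identical values, and each pair within a group differed by more than sampling noise. The chi-square per degree of freedom was 2.88 to 5.43 for pairs of flox macrophage libraries and 1.25 to 2.1 for pairs in the other groups. The fit shares the spread over all groups, so it may understate the spread in comparisons that use flox macrophages. Fold changes against groups with 3 or fewer counts are given as bounds against a floor of 3 counts over the group, or as ratios with a 95% exact counting interval, which cover counting error only.

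Genes were filtered with filterByExpr, which kept 13030, scaled with TMM (factors 0.929 to 1.06) and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. All 12 libraries were fitted together by group, with 8 residual degrees of freedom and no covariate. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, all tests two-sided unless stated. The standard error is the absolute log2 fold change divided by the square root of the F statistic. Contrasts were KO against flox in macrophages and in osteoclast cultures, RANKL in flox and in KO cells, and the difference between the RANKL responses. CPM values were computed from the deposited counts with the scaled library sizes.

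Of 28 gene lists, 7 of them markers of other cell types, 22 had at least 5 members past the filter and were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of 1 comparison. Lists not tested were catecholamine handling, mast cell and basophil, erythroid and adipocyte genes, and the sex-linked and knockout design genes, which are given singly. With an estimated correlation 12 of the 53 calls over the comparisons held. They were the macrophage, lipid handling, RANK and stromal lists for genotype in macrophages, the osteoclast, p53, RANK and stromal lists for genotype in osteoclast cultures, the macrophage list for RANKL in both genotypes, and the macrophage and p53 lists for the difference between responses. Genes named are Asxl2, Lyz2, sex-linked genes, up to 10 called genes per direction with the largest change whose groups did not overlap (this condition not applied to the difference between responses) and at least 5 CPM in the higher group, and up to 2 members of each tested list per direction by p. Gene model and pseudogene names were left out, and not every gene the rule gives is named. Some results are not reported here.

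The tests of the 5 comparisons, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The grouping of mitochondrially encoded genes, the splits of the libraries and several tests of explanations were chosen afterwards. The alternatives were RLE scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM in 3 libraries, fits of the compared groups alone, counts without mitochondrial and the 20 most abundant genes, a 2-fold minimum, the replicate number as a block and each library left out. For lists they were the estimated correlation, fry and a prior count of 0.5. The procedure was tested on simulated data with 200 changed genes, 50 at each fold. These sets had far fewer changed genes than were called in the data and the same spread in all groups. Their recovery may therefore differ from that in the data. False calls are set against all genes in the simulated fit, not against the calls made. At folds of 1.15, 1.3, 1.5 and 2 it recovered 50%, 70%, 86% and 92% for genotype in macrophages (9 false calls among 12903 genes), 50%, 72%, 86% and 94% in osteoclast cultures (12 of 12898). It recovered 50%, 76%, 90% and 92% for RANKL in flox cells (9 of 12676), 50%, 70%, 72% and 88% in KO cells (7 of 12680) and 18%, 56%, 72% and 88% for the difference between responses (7 of 12911). Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.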

Results

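Gene expression was measured by RNA sequencing in bone-marrow-derived cells of C57BL/6 mice with floxed Asxl2 alleles (flox) and of mice in which LysM-Cre, a recombinase expressed from the lysozyme locus in myeloid cells, acts on them (KO). ASXL2 is a chromatin protein of the additional sex combs family, a partner of the BAP1 deubiquitinase and of Polycomb-group proteins. Marrow cells were grown for 5 days on petri dishes, replated, and kept for 2 days in medium with 2% M-CSF, the macrophage growth factor. Macrophage cultures had M-CSF alone, and osteoclast cultures also had 50 ng/ml RANKL, the cytokine that drives the formation of osteoclasts, the bone-resorbing cells. Each of the 4 groups (flox macrophages, KO macrophages, flox osteoclast cultures, KO osteoclast cultures) had 3 libraries. Total counts were between 18489873 and 21667237 per library. The series' title places the work in a study of myeloid ASXL2 deletion, obesity on a rich diet and energy expenditure. The comparisons ask how KO differ from flox macrophages, how RANKL-treated cultures differ, and whether the response to RANKL depends on genotype. The labels do not say whether the flox mice carry Cre, so KO against flox may combine loss of Asxl2 with effects of Cre and of its insertion in Lyz2. The labels do not say whether the libraries of a group came from separate mice or cultures, so the p-values measure only the spread between these samples, which may be technical.

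The first principal component held 73.3% of the variance and separated macrophages from osteoclast cultures. Macrophage libraries lay between −47.5 and −41.5 on it, flox osteoclast cultures between 52.3 and 53.2, and KO osteoclast cultures between 38.5 and 38.9. The second component held 14.5% and separated genotypes. On it, flox libraries lay between −24 and −17.2 and KO libraries between 18.6 and 21.7.

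**Figure D1:**
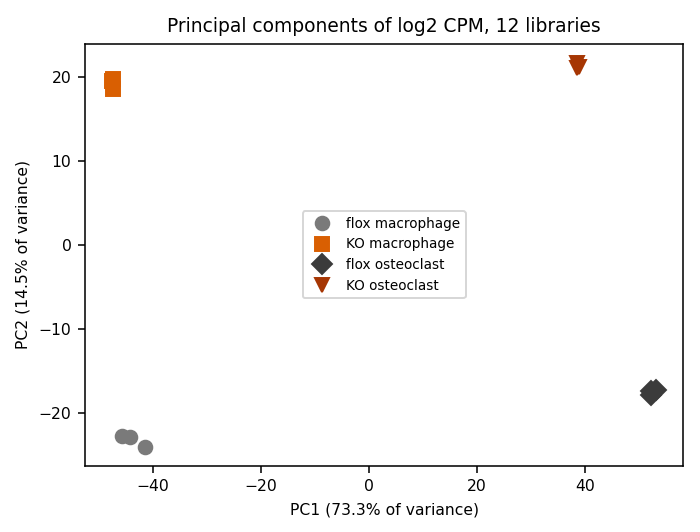
Principal components of log2 CPM for the 12 libraries, 3 per group, with the first component (73.3% of variance) on the horizontal axis and the second (14.5%) on the vertical axis. KO osteoclast cultures lie between 38.5 and 38.9 on the first component and flox osteoclast cultures between 52.3 and 53.2.

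Asxl2 itself (chromosome 12, 3426857 to 3506852, GRCm38) was lower in every KO library than in every flox library. In macrophages it fell from 93.2 ± 3.0 CPM (read counts scaled to a common library size, mean ± SD, n = 3 in each group) to 15.1 ± 0.26 CPM, a log2 fold change of −2.63 (SE 0.051, edgeR adjusted p = 1.34e-38). In osteoclast cultures it fell from 73.4 ± 2.3 to 13.7 ± 1.2 CPM, a log2 fold change of −2.42 (SE 0.053, edgeR adjusted p = 3.11e-36). Exact two-sided permutation tests gave p = 0.1 in both, the smallest that 3 libraries against 3 allow. The labels do not state which exons were removed, and reads of a shortened transcript would still count toward the gene. Lyz2, the lysozyme gene that carries LysM-Cre (chromosome 10, 117277334 to 117282274), was the most abundant gene in every library. It was slightly lower in KO macrophages (log2 fold change −0.16, SE 0.023, adjusted p = 2.25e-07) and slightly higher in KO osteoclast cultures (0.14, SE 0.023, adjusted p = 4.36e-06), and its neighbouring paralog Lyz1 can share reads with it. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y were present in all groups at means of 24.8 to 78.6 CPM, and Xist and Tsix never exceeded 1 count. Kdm5d was higher in KO cells by 0.33 in macrophages and 0.37 in osteoclast cultures on the log2 scale.

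KO macrophages had far less Emb and Pf4 than flox macrophages and more of the scavenger receptor gene Marco. Emb, which encodes embigin, a membrane chaperone of monocarboxylate transporters (chromosome 13, 117220625 to 117274098), fell from 131 ± 4.6 to 13.5 ± 0.14 CPM, a log2 fold change of −3.28 (SE 0.049, adjusted p = 1.54e-43). Pf4, a CXC chemokine gene (chromosome 5, 90772435 to 90773381), fell from 374 ± 32 to 49.9 ± 2.1 CPM (−2.90, SE 0.053, adjusted p = 2.31e-19). Marco (chromosome 1, 120474538 to 120505024) rose from 157 ± 2.0 to 510 ± 12 CPM (1.70, SE 0.03, adjusted p = 1.76e-40). Cbr2, a carbonyl reductase gene (chromosome 11, 120729489 to 120732114), rose from 65.9 ± 2.9 to 199 ± 7.2 CPM, and Padi4, a peptidylarginine deiminase gene (chromosome 4, 140745865 to 140774236), from 10.1 ± 1.5 to 34.2 ± 0.95 CPM. Among other large increases were the acute-phase gene Saa3 (log2 fold change 2.03), the Notch-modifying glycosyltransferase Mfng (1.82), the talin gene Tln2 (1.63), the tetraspanin Tspan32 (1.56), the cortactin gene Cttn (1.48), the sialic acid receptor Cd33 (1.46) and the Rag GTPase Rragd (1.32). Large decreases were seen for Tmem26 (−2.71), the protease inhibitor Spint1 (−2.36), the receptor Notch4 (−2.34), Cyp2s1 (−2.28), Tspan13 (−2.22), the integrin gene Itga8 (−2.19) and the caveolin gene Cav1 (−2.16).

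Across the genome, 5203 of 13030 genes tested (39.9%) differed by genotype in macrophages at an adjusted p under 0.05, 2513 higher and 2690 lower in KO cells. Most differences were small, with a median absolute log2 fold change of 0.262 among the called genes. At least 2-fold changes numbered 548, of which 116 were higher and 432 lower. Stromal genes such as Acta2 (−1.32) are among the decreases, and for these a carry-over of fewer stromal cells is a candidate explanation. The 3 KO libraries lay wholly above or wholly below the 3 flox libraries for 46.6% of genes, where chance gives 10%.

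**Figure D2:**
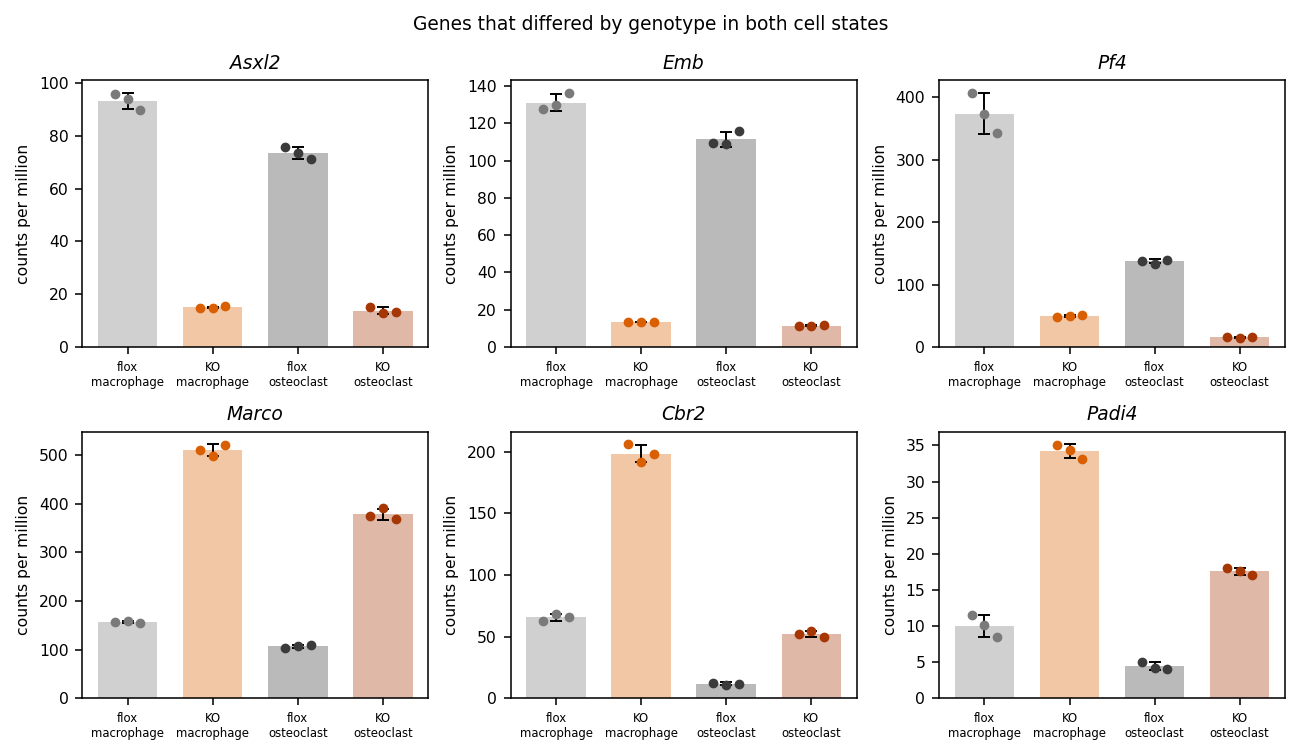
CPM of 6 genes in the 4 groups, with a point for each library, bars for the mean of 3 and error bars for the SD. Asxl2, Emb and Pf4 were lower and Marco, Cbr2 and Padi4 higher in KO cells in both cell states, for instance Marco at 510 against 157 CPM in macrophages and 378 against 107 CPM in osteoclast cultures.

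Gene lists fixed beforehand were compared with all other genes by camera, and counts of members adjusted over the list alone are given where they differ from those over all genes. Most cell cycle genes rose in KO macrophages, with 18 of 24 members higher, 3 lower and 3 not called (median log2 fold change 0.65, camera adjusted p = 4.46e-09, adjusted p = 0.059 with an estimated correlation). The members not called higher were Mcm2, Mcm3, Mcm5, Mcm6, Pcna and E2f1, whose KO means lay below the flox means. Cdc20, the anaphase-promoting complex activator, rose from 41.3 ± 2.2 to 86.8 ± 1.3 CPM and the cyclin gene Ccna2 from 172 ± 8.4 to 315 ± 2.9 CPM, while Pcna, the replication clamp, fell by 0.13 on the log2 scale. Nuclear-encoded oxidative phosphorylation genes also rose, with 22 of 33 higher and 11 not called, by small amounts (median 0.12, adjusted p = 3.16e-05, adjusted p = 0.129 with an estimated correlation). The ATP synthase genes Atp5a1 and Atp5b were each 0.18 higher on the log2 scale. Of 14 mitochondrially encoded genes, grouped after their values were seen, 0 were called higher and 5 lower (median −0.29). The median stayed between −0.36 and −0.17 under every alternative that kept these genes, but the count of calls moved. No lower call was made without flox macrophage library 2 or 3 or KO macrophage library 1 or 3, without a filter on low counts, or in a fit of the macrophage libraries alone. The count was 8 with DESeq2, 9 with limma-voom, 8 without flox macrophage library 1, 3 without flox osteoclast library 1 or 3, 2 without KO osteoclast library 3 and 1 without flox osteoclast library 2.

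Macrophage genes fell in KO macrophages, 16 of 22 lower, 5 higher and 1 not called (median −0.21, adjusted p = 8.09e-05, adjusted p = 0.0208 with an estimated correlation). The fatty acid receptor gene Cd36 fell from 1910 ± 75 to 1210 ± 28 CPM and the macrophage surface receptor gene Adgre1 from 2090 ± 29 to 1560 ± 24 CPM. The chemokine receptor Ccr2 rose by 0.55 and the efferocytosis receptor Mertk by 0.22. RANK and NF-kB signalling genes were lower for 12 of 18 members, higher for 1 and not called for 5 (median −0.26, adjusted p = 3.82e-05, adjusted p = 0.0208 with an estimated correlation), among them the non-canonical NF-kB subunits Relb (−0.86) and Nfkb2 (−0.58). Lipid handling genes were lower for 13 of 22, higher for 3 and not called for 6, with 15 lower and 4 higher adjusted over the list alone (median −0.17, adjusted p = 0.000941, adjusted p = 0.0248 with an estimated correlation). The lipoprotein lipase gene Lpl fell by 0.61 on the log2 scale, and the lysosomal cholesterol transporter Npc1 rose by 0.20.

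Osteoclast genes were lower for 8 of 18 members, higher for 4 and not called for 6, with 9 lower adjusted over the list alone (median −0.43, adjusted p = 0.0311, adjusted p = 0.0893 with an estimated correlation). The fusion genes Dcstamp (−1.53) and Atp6v0d2 (−1.10) fell, and Nfatc1, the master transcription factor of osteoclasts, was 0.23 higher. Inflammatory genes were lower for 9 of 16, higher for 4 and not called for 3 (median −0.47, adjusted p = 0.0144, adjusted p = 0.059 with an estimated correlation). The NF-kB feedback genes Tnfaip3 (−0.77) and Nfkbia (−0.48) fell, whereas the monocyte chemokines Ccl7 (1.23) and Ccl2 (1.03) rose. Interferon response genes were lower for 15 of 24 and not called for 9, with 17 lower adjusted over the list alone (median −0.20, adjusted p = 8.09e-05, adjusted p = 0.237 with an estimated correlation), including Rsad2 (−0.55). Immediate early and heat shock genes were lower for 9 of 16 and not called for 7 (median −0.37, adjusted p = 0.000349, adjusted p = 0.059 with an estimated correlation), with Junb at −0.64 and Egr2 at −1.21. MHC class II genes were lower for 5 of 8 and not called for 3 (median −0.42, adjusted p = 0.0063, adjusted p = 0.129 with an estimated correlation). The invariant chain gene Cd74 fell from 211 ± 7.7 to 108 ± 3.5 CPM.

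Cholesterol synthesis genes were lower in KO macrophages for 14 of 21, higher for 1 and not called for 6, with 15 lower adjusted over the list alone (median −0.23, adjusted p = 8.09e-05, adjusted p = 0.0858 with an estimated correlation). The sterol enzymes Msmo1 and Cyp51 fell by 0.73 and by 0.62 on the log2 scale. Alternative activation genes were lower for 7 of 12, higher for 2 and not called for 3, with 8 lower adjusted over the list alone (median −0.34, adjusted p = 0.0311, adjusted p = 0.107 with an estimated correlation). Pparg was at −0.78 and the transglutaminase gene Tgm2 at 0.81. Without flox macrophage library 1 this list's adjusted p was 0.0545. Lists that did not pass were fatty acid oxidation (7 higher, 2 lower, 12 not called, median 0.05 but mean −0.02, camera direction up, adjusted p = 0.244) and Polycomb and BAP1 complex genes (8, 4 and 10, median 0.06, adjusted p = 0.441). Neither did p53 targets (3, 3 and 8, median 0.03, adjusted p = 0.733) or Hox genes (2 lower, 3 not called, median −0.24, adjusted p = 0.0798). Glycolysis and hypoxia genes (1 higher, 9 lower, 9 not called, median −0.15) had an adjusted p of 0.0654, and 0.0143 without flox macrophage library 3. Secreted metabolic factor genes (5 higher, 8 lower, 3 not called, median −0.19) had an adjusted p of 0.0749, which was 0.0301 without flox macrophage library 3 and 0.0483 without KO macrophage library 2. Within these lists Acadl, a fatty acid oxidation enzyme gene, rose by 0.35, the mitochondrial carrier gene Ucp2 fell by 0.42. The Polycomb genes Jarid2 and Bmi1 fell by 0.59 and by 0.57, Vegfa rose by 0.80 and the growth factor gene Pdgfb fell by 0.98 on the log2 scale.

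Markers of other cell types differed between the macrophage groups as well. All 10 tested stromal and osteoblast markers were lower in KO macrophage cultures (median −1.64, adjusted p = 6.22e-08, adjusted p = 0.0208 with an estimated correlation). The collagen gene Col1a2 was at 69.0 ± 4.6 against 21.3 ± 1.6 CPM and Sparc at 31.5 ± 1.9 against 10.4 ± 0.83 CPM. Neutrophil markers were lower for 4 of 7 and not called for 3, with 5 lower adjusted over the list alone (median −0.94, adjusted p = 0.00967, adjusted p = 0.059 with an estimated correlation), S100a9 at 1.86 against 0.642 CPM. B and T lymphocyte markers were lower for 3 of 5 and not called for 2 (median −0.69, adjusted p = 0.0248, adjusted p = 0.0858 with an estimated correlation), Ighm at 25.5 against 16.7 CPM. Dendritic cell markers (2 lower, 4 not called, median −0.07) had an adjusted p of 0.377. Catecholamine handling, mast cell, erythroid and adipocyte lists had under 5 members past the expression filter and were not tested.

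KO osteoclast cultures had less of the osteoclast genes Acp5 and Jdp2 and more of the macrophage gene Maf than flox osteoclast cultures. Acp5, which encodes tartrate-resistant acid phosphatase (chromosome 9, 22126731 to 22135746), fell from 132 ± 3.8 to 40.8 ± 1.3 CPM, a log2 fold change of −1.70 (SE 0.04, adjusted p = 2.83e-35). Jdp2, an AP-1 family transcription factor gene (chromosome 12, 85599105 to 85639878), fell from 163 ± 3.8 to 56.8 ± 2.5 CPM (−1.52, SE 0.038, adjusted p = 6.73e-34). Prdm1, which encodes the repressor Blimp1 (chromosome 10, 44437177 to 44528501), fell from 39.3 ± 2.5 to 7.59 ± 0.95 CPM (−2.37, SE 0.075, adjusted p = 1.1e-29). Maf (chromosome 8, 115682942 to 115707794) rose from 53.7 ± 1.1 to 118 ± 3.3 CPM (1.13, SE 0.036, adjusted p = 8.02e-30). Emb (111 ± 4.0 to 11.5 ± 0.44 CPM) and Pf4 (137 ± 3.4 to 15.5 ± 0.52 CPM) fell here too, and Marco (107 ± 2.9 to 378 ± 11 CPM) and Cbr2 (11.9 ± 1.1 to 52.2 ± 2.6 CPM) rose.

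Among genes that met the naming rule, the largest decrease in osteoclast cultures by ratio was that of Eya1, a transcriptional co-activator and phosphatase gene. It had 3 counts over the KO libraries against 332 over the flox libraries, 105-fold lower (95% counting interval 35.6 to 511). Pgf, the placental growth factor gene (chromosome 12, 85166639 to 85177296), fell from 15.2 ± 0.71 to 0.739 ± 0.18 CPM (−4.35). Further large decreases were those of the semaphorin receptor Plxna4 (−2.70), the actin-severing gene Scin (−2.65) and Cyp2s1 (−2.58). Increases included Mfng (2.20), Padi4 (1.96), Cd33 (1.94), Tspan32 (1.93), Mcemp1 (1.82), Zfp618 (1.79), the transcription factor gene Lyl1 (1.71) and the inhibitory receptor Cd300lf (1.69). In all, 5381 of 13030 genes (41.3%) differed, 2786 higher and 2595 lower in KO cultures, with a median absolute log2 fold change of 0.253 among them. Changes of at least 2-fold numbered 550, 195 higher and 355 lower, and libraries of the genotypes did not overlap for 51.3% of genes. Stromal genes such as Acta2 (−1.34) are among the decreases here too, with the same candidate explanation.

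Osteoclast genes fell as a group in KO osteoclast cultures, with 15 of 18 lower, 1 higher and 2 not called, and 16 lower adjusted over the list alone (median −0.64, camera adjusted p = 6e-07, adjusted p = 0.011 with an estimated correlation). Clcn7, the lysosomal chloride exchanger gene, was at 233 ± 2.9 and 236 ± 1.6 CPM and did not pass the test, and Ostm1, its partner subunit, was 0.15 higher on the log2 scale. RANK and NF-kB signalling genes fell for 10 of 18 and were not called for 8 (median −0.16, adjusted p = 6.44e-05, adjusted p = 0.0147 with an estimated correlation), with the calcineurin regulator Rcan1 at −1.29. The p53 target list fell as well, with 9 of 14 lower and 5 not called (median −0.29, adjusted p = 0.000309, adjusted p = 0.0153 with an estimated correlation). Among its lower members were Mdm2, the p53 ubiquitin ligase (779 ± 3.6 to 438 ± 17 CPM), and Cdkn1a, a cyclin-dependent kinase inhibitor (558 ± 14 to 362 ± 9.4 CPM). Macrophage genes went the other way, with 12 of 22 higher, 6 lower and 4 not called, and 13 higher adjusted over the list alone (median 0.11, adjusted p = 0.0405, adjusted p = 0.104 with an estimated correlation). Besides Maf, Mertk rose from 17.0 ± 0.36 to 34.3 ± 0.92 CPM, whereas Axl fell by 0.93 and Cd36 by 0.57 on the log2 scale.

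Cell cycle genes were again mostly higher in KO cells, for 16 of 24 members against 4 lower and 4 not called (median 0.24, adjusted p = 0.00135, adjusted p = 0.257 with an estimated correlation), Cdc20 at 0.64 and the mitotic kinase gene Plk1 at 0.58. Mcm5, Mcm6, Pcna and E2f1 lay lower in every KO than in every flox osteoclast library. Immediate early and heat shock genes fell for 9 of 16 and were not called for 7 (median −0.26, adjusted p = 0.000309, adjusted p = 0.06 with an estimated correlation), with Egr2 at −1.14 and Junb at −0.46. MHC class II genes fell for 5 of 8 and were not called for 3 (median −0.26, adjusted p = 0.0405, adjusted p = 0.266 with an estimated correlation), Cd74 at −0.95. Inflammatory genes fell for 9 of 16, rose for 4 and were not called for 3, with 10 lower adjusted over the list alone (median −0.23, adjusted p = 0.0432, adjusted p = 0.102 with an estimated correlation). The cytokine signalling inhibitor Socs3 fell by 1.98 on the log2 scale, and Ccl2 rose by 1.61. This list's adjusted p was 0.0728 without flox macrophage library 1 and 0.0511 without flox osteoclast library 1. Lipid handling genes were lower for 6 of 22, higher for 5 and not called for 11, with 7 lower adjusted over the list alone (median −0.07, adjusted p = 0.0464, adjusted p = 0.102 with an estimated correlation). The lipoprotein gene Apoe fell by 0.67 and Gpnmb by 0.55, and the lysosomal lipase gene Lipa rose by 0.22. With any single one of KO macrophage libraries 1, 2 and 3, flox osteoclast libraries 1 and 2, or KO osteoclast library 3 left out, the lipid list's adjusted p was 0.05 to 0.0651.

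Lists that did not pass in osteoclast cultures were interferon response (10 higher, 2 lower, 12 not called, median 0.07, adjusted p = 0.123) and oxidative phosphorylation (1, 5 and 27, with 0 higher and 2 lower adjusted over the list alone, median −0.03, adjusted p = 0.274). Fatty acid oxidation (8, 4 and 9, median 0.06, adjusted p = 0.127), cholesterol synthesis (3, 6 and 12, median −0.02, adjusted p = 0.329) and alternative activation genes (2, 7 and 3, median −0.28, adjusted p = 0.134) did not pass either. The same held for Polycomb and BAP1 complex genes (7, 3 and 12, median 0.08, adjusted p = 0.402) and Hox genes (1 lower, 4 not called, median −0.27, adjusted p = 0.164). Secreted metabolic factors (6, 5 and 5, median 0.10 but mean −0.26, camera direction up) had an adjusted p of 0.763. Glycolysis and hypoxia genes (2, 9 and 8, with 11 lower adjusted over the list alone, median −0.13) had an adjusted p of 0.119, which was 0.0439 without flox macrophage library 1 and 0.0484 without flox macrophage library 3. Among their members Metrnl, a secreted factor gene, rose by 0.53, Grn by 0.36 and Vegfa by 0.85, while Jarid2 fell by 0.40 and Ucp2 by 0.37 on the log2 scale. All 10 stromal markers were lower here too (median −1.55, adjusted p = 8.69e-08, adjusted p = 0.0153 with an estimated correlation), Col1a2 at 52.1 against 17.6 CPM. Neutrophil markers were lower for 5 of 7, higher for 1 and not called for 1, with 6 lower adjusted over the list alone (median −1.33, adjusted p = 0.0405, adjusted p = 0.102 with an estimated correlation, and 0.0511 without flox osteoclast library 1). Lymphocyte markers did not pass (2 lower, 3 not called, median −0.60, adjusted p = 0.274). Nor did dendritic cell markers (2 lower, 4 not called, median 0.01 but mean −0.31, camera direction down, adjusted p = 0.595).

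**Figure D3:**
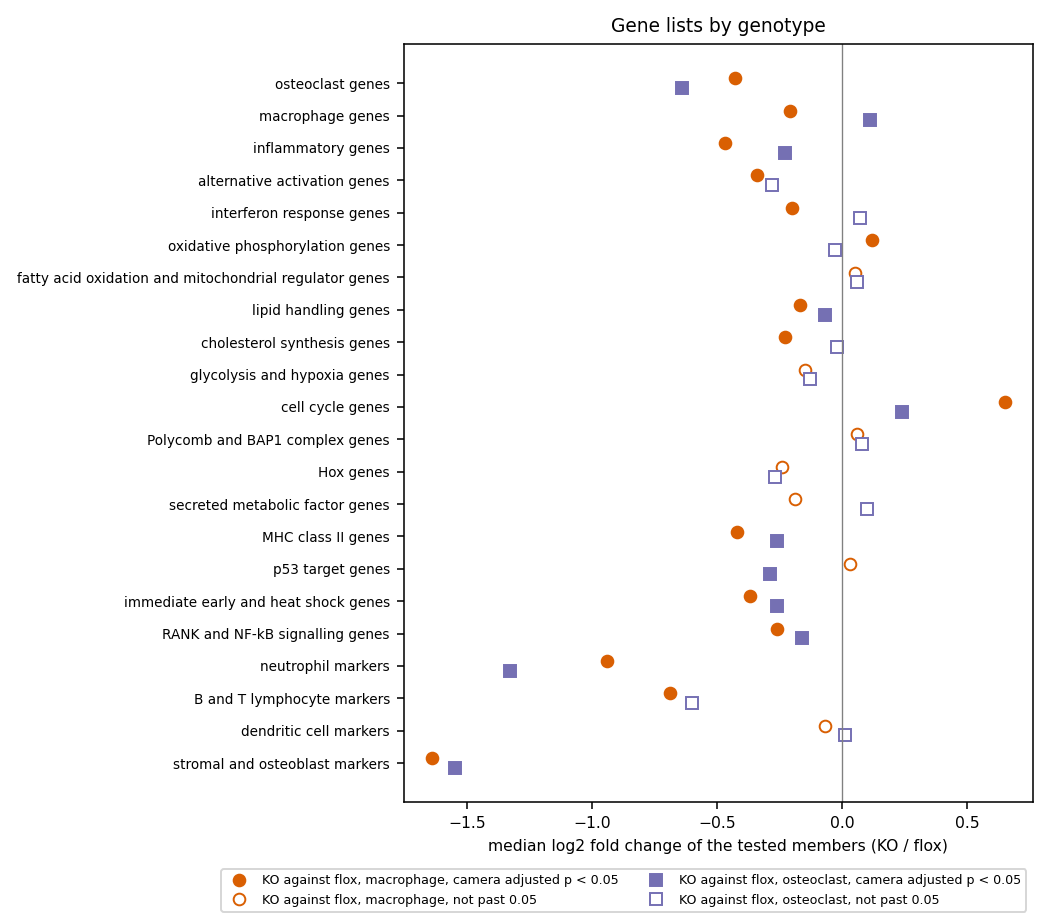
Median log2 fold change (KO over flox, horizontal axis) of the tested members of 22 gene lists, in macrophages (circles) and osteoclast cultures (squares), filled where the camera adjusted p passed 0.05. Stromal markers lie farthest to the left (−1.64 and −1.55), and cell cycle genes in macrophages farthest to the right (0.65).

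Genotype differences were shared by the cell states, which have no library in common. Cultures of both states may come from the same marrow, so a difference between the flox and KO preparations would recur in both. The Fisher tests below treat genes as independent, which they are not. Of the called genes, 1435 were higher in KO cells in both, where 537 would be shared by chance (odds ratio 9.03, −log10 of the one-sided Fisher p 442), and 1413 were lower in both against 536 by chance (odds ratio 8.57, −log10 p 422). Emb, Pf4, Cyp2s1 and Asxl2 were among the shared decreases, and Marco, Cbr2, Padi4, Mfng, Cd33 and Tspan32 among the shared increases. Another 314 genes were called in opposite directions, Lyz2 among them. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.656 and a Spearman rho of 0.489.

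RANKL treatment of flox cells raised Mycl, Jdp2 and Nfatc1 and lowered Slco2b1 and Maf. Mycl, a Myc-family transcription factor gene (chromosome 4, 122995652 to 123002485), rose from 0.418 ± 0.12 to 101 ± 2.9 CPM, a log2 fold change of 7.89 (SE 0.1, adjusted p = 1.84e-47). Jdp2 rose from 10.0 ± 1.3 to 163 ± 3.8 CPM (4.02, SE 0.053, adjusted p = 3.77e-47) and Nfatc1 (chromosome 18, 80606205 to 80713071) from 99.3 ± 2.6 to 350 ± 1.8 CPM (1.82, SE 0.031, adjusted p = 6.29e-43). The organic anion transporter Slco2b1 (chromosome 7, 99657804 to 99711340) fell from 52.9 ± 4.6 to 0.795 ± 0.057 CPM (−6.04, SE 0.11, adjusted p = 3.07e-41), and Maf from 806 ± 22 to 53.7 ± 1.1 CPM (−3.91, SE 0.034, adjusted p = 1.16e-54). Slc6a4, the serotonin transporter gene, had no count in flox macrophages and 482 in flox osteoclast cultures, at least 140-fold higher against a floor of 3 counts over the group, and Gfi1b had 1 count against 794, 692-fold higher (95% counting interval 124 to 27400). Other large increases were Pgf (6.08), Vegfc (5.83), Cyp2ab1 (5.53), Zbtb32 (5.50), the hepatocyte growth factor receptor Met (5.38) and Diras2 (5.13). Decreases included Gpr34 (−5.53), the prostaglandin-degrading enzyme Hpgd (−4.96), the haemoglobin scavenger receptor Cd163 (−4.72), the purinergic receptor P2ry13 (−4.46), Fcrls (−4.22), Plxdc2 (−4.21) and Tpbgl (−3.99). Rnase4 fell from 354 ± 11 to 19.4 ± 1.3 CPM, but it shares its start with Ang, so the split of reads between them is uncertain. In all, 9747 of 13030 genes (74.8%) were called, 4822 higher and 4925 lower. At least 2-fold changes numbered 2267 (895 higher, 1372 lower), and the groups' libraries did not overlap for 75.2% of genes.

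RANKL changed 9182 genes in KO cells (70.5%), 4627 higher and 4555 lower, of which 796 rose and 1015 fell at least 2-fold. Mycl rose from 0.121 ± 0.087 to 70.2 ± 2.9 CPM (9.15, SE 0.13, adjusted p = 2.33e-45), and Jdp2 from 10.7 ± 0.2 to 56.8 ± 2.5 CPM (2.40, SE 0.06, adjusted p = 1.23e-35). Maf fell from 852 ± 17 to 118 ± 3.3 CPM (−2.86, SE 0.031, adjusted p = 1.39e-50) and Slco2b1 from 12.4 ± 0.23 to 0.251 ± 0.15 CPM (−5.59, SE 0.2, adjusted p = 4.18e-29). Slc6a4 had 1 count in KO macrophages and 305 in KO osteoclast cultures, 306-fold higher (95% counting interval 54.5 to 12100). Gfi1b (7.23), Diras2 (6.15), the splicing regulator Rbfox1 (5.96), Zbtb32 (5.91), Vegfc (5.88), Met (5.67) and Cyp2ab1 (5.46) also rose, and Gpr34 (−4.88), Cd163 (−4.32), Hpgd (−4.28), P2ry13 (−4.01), Tpbgl (−3.65), Plxdc2 (−3.57), Fcrls (−3.57), P2ry12 (−3.51) and Prr5l (−3.42) fell. Of 8222 genes called for RANKL in both genotypes, 8122 moved in the same direction. Across genes, the log2 fold changes of the genotypes had a Pearson r of 0.919 and a Spearman rho of 0.901, with a total least squares slope of 0.915 (KO on flox).

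**Figure D4:**
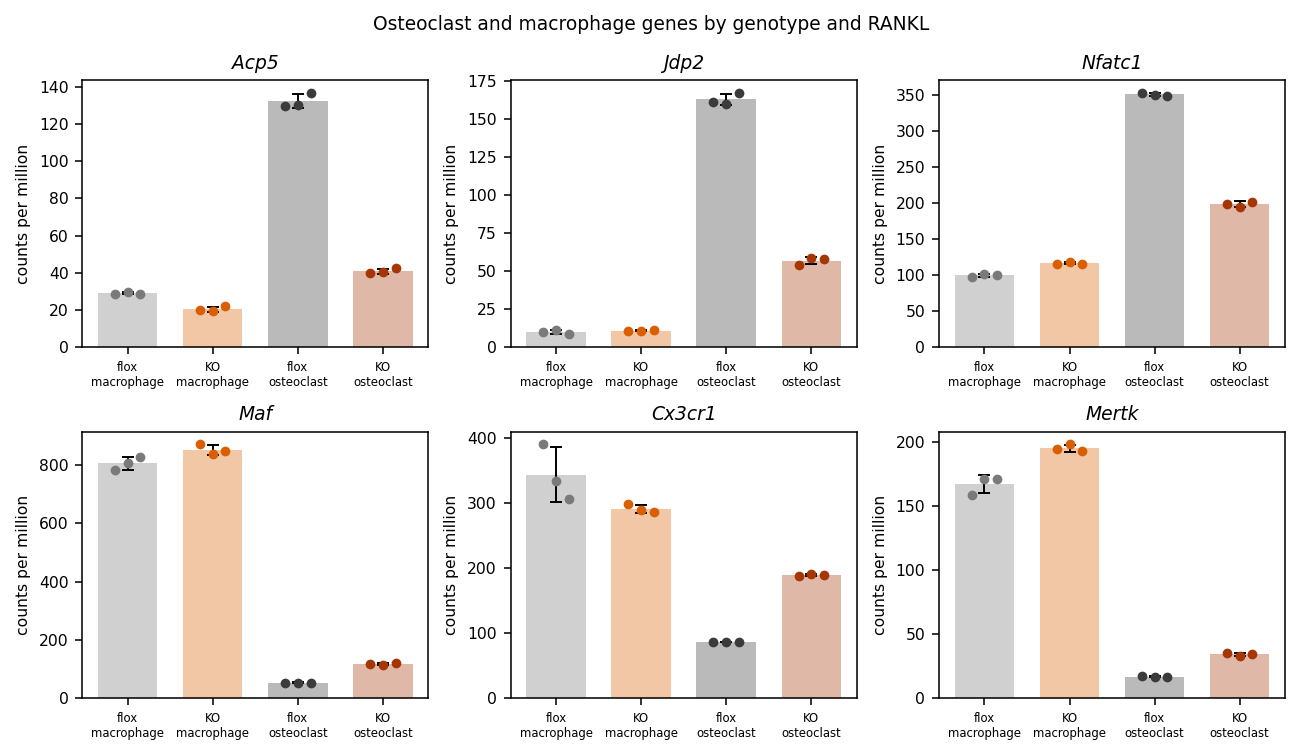
CPM of 6 osteoclast and macrophage genes in the 4 groups, with a point for each library, bars for the mean of 3 and error bars for the SD. Acp5, Jdp2 and Nfatc1 reach 132, 163 and 350 CPM in flox but 40.8, 56.8 and 198 CPM in KO osteoclast cultures, while Maf, Cx3cr1 and Mertk stay higher in KO than in flox osteoclast cultures.

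Macrophage genes fell with RANKL for all 22 members in flox cells (median −1.91, camera adjusted p = 8.21e-12, adjusted p = 0.00182 with an estimated correlation). They fell for 20 of 22 in KO cells, with 2 not called (median −1.47, adjusted p = 5.24e-11, adjusted p = 0.00233 with an estimated correlation). The complement genes C1qa in flox and C1qc in KO cells fell by 2.39 and by 1.83 on the log2 scale. Osteoclast genes rose for 14 of 18 and fell for 4 in flox cells (median 0.50, adjusted p = 0.016, adjusted p = 0.0947 with an estimated correlation). In KO cells 11 rose, 3 fell and 4 were not called (median 0.63, adjusted p = 0.0441, adjusted p = 0.223 with an estimated correlation, and 0.0567 without flox macrophage library 1), the gelatinase gene Mmp9 at 3.70. The creatine kinase gene Ckb went against the list in both (−1.42 in flox, −1.20 in KO). RANK and NF-kB genes rose for 11 of 18 in flox cells, with 4 lower and 3 not called (median 0.19, adjusted p = 0.0227, adjusted p = 0.0947 with an estimated correlation). In KO cells 12 rose, with 4 lower and 2 not called (median 0.34, adjusted p = 0.0393, adjusted p = 0.198 with an estimated correlation). Nfkb2 (2.34) and the adaptor Traf3 (1.41) were among those that rose in flox cells.

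With RANKL, cell cycle genes rose for 23 of 24 members in flox cells and fell for 1 (median 0.59, adjusted p = 1.38e-06, adjusted p = 0.114 with an estimated correlation). They rose for 21 and fell for 1 in KO cells, with 2 not called (median 0.22, adjusted p = 0.00107, adjusted p = 0.332 with an estimated correlation). The ubiquitin-conjugating enzyme gene Ube2c rose by 1.42 in flox and by 0.75 in KO cells. Oxidative phosphorylation genes rose for 29 of 33 in flox cells, with 1 lower and 3 not called (median 0.26, adjusted p = 5.37e-05, adjusted p = 0.217 with an estimated correlation). In KO cells 20 rose, with 2 lower and 11 not called (median 0.12, adjusted p = 0.0305, adjusted p = 0.571 with an estimated correlation). The cytochrome gene Cyc1 rose by 0.77 in flox and by 0.56 in KO cells. Of the 14 mitochondrially encoded genes, 3 were lower and 0 higher in flox cells (median −0.13, with 6 lower by limma-voom), and 8 were higher and 0 lower in KO cells (median 0.40). Under the alternatives that kept these genes the medians were −0.19 to −0.06 in flox and 0.31 to 0.46 in KO cells. In flox cells p53 targets rose for 11 of 14, with 2 lower and 1 not called (median 0.29, adjusted p = 0.0189, adjusted p = 0.0947 with an estimated correlation), Mdm2 by 2.16 and the exonuclease gene Aen by 1.28. In KO cells the p53 list (7 higher, 5 lower, 2 not called, with 6 lower adjusted over the list alone, median 0.02) had an adjusted p of 0.573. MHC class II genes fell for all 8 members in both genotypes (medians −0.76 and −0.85, adjusted p = 0.00722 and 0.00781, adjusted p = 0.207 and 0.254 with an estimated correlation). Lipid handling genes fell for 12 of 22 in flox cells, with 5 higher and 5 not called and 13 lower adjusted over the list alone (median −0.41, adjusted p = 0.0227, adjusted p = 0.0947 with an estimated correlation). In KO cells 14 fell, 5 rose and 3 were not called (median −0.44, adjusted p = 0.0305, adjusted p = 0.198 with an estimated correlation), with Cd36 at −1.69 in flox and −1.60 in KO cells and the sterol receptor Nr1h3 at 0.71 and 1.07. Cholesterol synthesis genes fell for 16 of 21 in flox cells, with 3 higher and 2 not called (median −0.56, adjusted p = 0.00398, adjusted p = 0.217 with an estimated correlation). In KO cells 14 of them fell, with 4 higher and 3 not called (median −0.30, adjusted p = 0.0305, adjusted p = 0.453 with an estimated correlation). Hmgcs1 was at −1.03 in flox and −0.80 in KO cells. Interferon response genes fell for 17 of 24 in flox cells, with 6 higher and 1 not called (median −0.35, adjusted p = 0.0342, adjusted p = 0.588 with an estimated correlation), Stat2 at −0.93. Secreted metabolic factors fell for 11 of 16 in both genotypes, with 4 higher and 1 not called in each (medians −0.65 and −0.46, adjusted p = 0.0282 and 0.0441, adjusted p = 0.325 and 0.453 with an estimated correlation). The growth factor gene Igf1 was at −1.76 in flox cells. In KO cells this list's adjusted p was 0.0577 without flox macrophage library 1 and 0.0558 without KO macrophage library 2.

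Other lists did not pass for RANKL, nor did the interferon list in KO cells. Inflammatory genes had 6 higher, 8 lower and 2 not called in each genotype (adjusted p = 0.709 in flox and 0.893 in KO cells), with medians of −0.34 and −0.17, and in KO cells a mean of 0.02 and a camera direction of down. The chemokine gene Cxcl10 rose by 3.06 in flox and 4.23 in KO cells, and Ccl4 fell by 3.36 and by 2.95 on the log2 scale. Immediate early and heat shock genes (9 higher, 5 lower and 2 not called in flox cells, 9 and 7 in KO cells) had medians of 0.51 and 0.56 (adjusted p = 0.243 and 0.345). In flox cells Junb was at 1.72 and the stress transcription factor gene Atf3 at −2.09. Glycolysis and hypoxia genes (9 higher, 9 lower and 1 not called in flox cells, 9, 8 and 2 in KO cells) had medians of 0.09 and 0.15 with means of −0.13 and −0.09 and a camera direction of up (adjusted p = 0.892 and 0.673). Ldha was at 0.80 and Hk2 at −1.67 in flox cells. Interferon response genes in KO cells (7, 10 and 7, median 0.02 but mean −0.07, camera direction down) had an adjusted p of 0.95. Alternative activation genes had 3 higher, 6 lower and 3 not called in flox cells and 4, 6 and 2 in KO cells (medians −0.66 and −0.79, adjusted p = 0.391 and 0.573). Fatty acid oxidation genes had 5, 11 and 5 in flox and 6, 8 and 7 in KO cells (medians −0.09 and −0.04, adjusted p = 0.44 and 0.573). Polycomb genes had 12, 8 and 2 in flox and 11, 7 and 4 in KO cells (medians 0.16 and 0.06, adjusted p = 0.517 and 0.491). Hox genes (1 higher, 1 lower and 3 not called in flox cells, 1 lower and 4 not called in KO cells) had medians of −0.14 and −0.30 (adjusted p = 0.709 and 0.491). Marker lists of other cells did not pass either. Stromal markers were higher for 1 and lower for 5 of 10 in flox cells and for 1 and 3 in KO cells (medians −0.32 and −0.26, adjusted p = 0.475 and 0.602). Neutrophil markers were lower for 3 of 7 in both, with 2 lower adjusted over the list alone in KO cells (medians −0.11 and −0.33, adjusted p = 0.34 and 0.345). Lymphocyte markers were higher for 1 of 5 in both and lower for 3 in flox and 2 in KO cells (medians −1.03 and −0.33, adjusted p = 0.263 and 0.453). Dendritic cell markers had 1 higher, 2 lower and 3 not called in flox cells, with only the 2 lower called adjusted over the list alone, and 2, 2 and 2 in KO cells (medians 0.15 and 0.12, means −0.22 and −0.40, camera direction down, adjusted p = 0.709 and 0.859).

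The RANKL response itself differed by genotype for 2850 of 13030 genes (21.9%), higher in KO cells for 1607 and lower for 1243 on the signed log2 scale. Nfatc1, Jdp2 and Acp5 responded less in KO cells. Nfatc1 reached 350 ± 1.8 CPM in flox but 198 ± 3.8 CPM in KO osteoclast cultures from macrophage levels of 99.3 ± 2.6 and 116 ± 1.8 CPM, a difference of responses of −1.05 (SE 0.043, adjusted p = 1.09e-23). The differences for Jdp2 (−1.62, SE 0.095, adjusted p = 1.87e-18) and Acp5 (−1.19, SE 0.072, adjusted p = 4.71e-18) had the same sign. Maf and Cx3cr1 were lowered less. Maf had a difference of 1.05 (SE 0.045, adjusted p = 2.87e-23). The fractalkine receptor gene Cx3cr1 fell from 343 ± 42 to 86.6 ± 0.46 CPM in flox but from 291 ± 6.1 to 189 ± 1.6 CPM in KO cells (1.37, SE 0.11, adjusted p = 1.34e-05).

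Among genes that met the naming rule, Plxna4 had the most negative difference of responses (−2.40), with 1.70 to 26.1 CPM in flox and 1.39 to 4.0 CPM in KO cells. Besides Jdp2 and Acp5, other negative differences were those of the membrane protease St14 (−1.79), Oaf (−1.21), the chemokine receptor Ccr1 (−1.20), the aminoacylase gene Acy1 (−1.20), Socs3 (−1.15), Bbs9 (−1.15) and Mdm1 (−1.11). Positive differences included Tmem26 (1.97), Ch25h (1.90), Bcar1 (1.88), Cav1 (1.86), Tmem176b (1.78), Lrrc4 (1.52), Zfp618 (1.47), Nt5e (1.44) and Tnip3 (1.4). A positive difference does not mean a higher level in KO osteoclast cultures. Tmem26 rose from 8.47 to 72.6 CPM in flox and from 1.29 to 43.6 CPM in KO cells. Cav1 rose from 51.6 to 497 CPM in flox and from 11.6 to 406 CPM in KO cells. Both were thus lower in KO cells in both states, whereas Zfp618 was higher in KO osteoclast cultures. Of the 138 genes whose responses differed at least 2-fold, 104 had a positive and 34 a negative difference. Among the 2850 genes, 2628 also responded to RANKL in flox cells, and for 2284 of these (86.9%) the difference ran against the flox response, 1022 of 1250 genes raised and 1262 of 1378 genes lowered by RANKL. Both measures use the flox libraries, and 10 simulated sets without any interaction gave 62.5% among genes with an unadjusted p under 0.05, a looser threshold than that of the observed calls. Independent lists of the same sizes would share 460 and 607 genes. The covariance of the difference with the flox response was −0.132 against −0.031 in the simulated sets, and since 3 libraries cannot be split into parts of at least 2 each, part of the excess may come from the shared libraries. Of the 2850 genes, 2112 were also called for RANKL in the same direction in both genotypes, and 1768 of these (83.7%) had a smaller response in KO cells when set against the mean response of the genotypes. This did not hold for the genes induced most: of 231 with a mean log2 response of at least 2, 23 were called weaker and 40 stronger in KO cells (median difference 0.26). The response is a ratio to the macrophage level, which was lower in KO cells for these genes (median −0.62), and in osteoclast cultures 133 of them were called lower and 29 higher in KO cells (median −0.45). Of 261 genes lowered as much, 104 were called weaker and 2 stronger (median difference 0.43).

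By list, macrophage genes had a positive difference for 17 of 22 members, a negative one for 2 and none called for 3, with 18 positive adjusted over the list alone (median 0.37, camera adjusted p = 3.84e-11, adjusted p = 0.00246 with an estimated correlation). Cd14 was at 0.65 and the mannose receptor Mrc1 at −0.44. The p53 targets had a negative difference for 10 of 14 with 4 not called, and 1 positive adjusted over the list alone (median −0.36, adjusted p = 2.78e-06, adjusted p = 0.00804 with an estimated correlation), Mdm2 at −0.63 and Cdkn1a at −0.57. Osteoclast genes had 8 negative, 2 positive and 8 not called, with 4 positive adjusted over the list alone (median −0.09, adjusted p = 0.00511, adjusted p = 0.064 with an estimated correlation), and Tnfrsf11a, which encodes RANK, was at 0.37. Cell cycle genes had 18 negative and 6 not called, with 1 positive adjusted over the list alone (median −0.41, adjusted p = 3.84e-11, adjusted p = 0.0637 with an estimated correlation), Ube2c at −0.66 and Ccna2 at −0.52. The median genotype difference of this list was still positive in both cell states (0.65 in macrophages and 0.24 in osteoclast cultures). Oxidative phosphorylation genes had 18 negative and 15 not called, with 19 negative adjusted over the list alone (median −0.14, adjusted p = 2.49e-08, adjusted p = 0.149 with an estimated correlation), Atp5b at −0.19 and Cox8a at −0.21. Interferon response genes had 15 positive and 9 not called, with 17 positive adjusted over the list alone (median 0.34, adjusted p = 1.44e-07, adjusted p = 0.24 with an estimated correlation), among them the RNA sensor genes Ifih1 (0.45) and Ddx58 (0.34). Cholesterol synthesis genes had 8 positive, 1 negative and 12 not called (median 0.15, adjusted p = 0.00137, adjusted p = 0.24 with an estimated correlation).

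Secreted metabolic factors had 7 positive, 3 negative and 6 not called, with 4 negative adjusted over the list alone (median 0.16, adjusted p = 0.0637), with the osteopontin gene Spp1 at 0.95 and Metrnl at 0.61. The adjusted p was 0.0126 without flox macrophage library 3, 0.0469 without KO macrophage library 2 and 0.0425 without flox osteoclast library 1. RANK and NF-kB genes moved both ways, with 6 positive, 5 negative and 7 not called, and 7 and 6 adjusted over the list alone (median 0.01, mean −0.03, camera direction down, adjusted p = 0.832). Relb was at 0.85 and Nfkb2 at 0.45 against Rcan1 at −0.84 and Tfec at −0.79. The remaining lists did not pass. Inflammatory genes had 4 positive, 2 negative and 10 not called, with 5 positive adjusted over the list alone (median 0.16, adjusted p = 0.36). Lipid handling genes had 7, 4 and 11, with 5 negative adjusted over the list alone (median 0.04, adjusted p = 0.692), and alternative activation 3, 1 and 8 (median 0.11, adjusted p = 0.692). Immediate early genes had 4, 2 and 10, with 5 and 3 adjusted over the list alone (median 0.09, adjusted p = 0.832). Fatty acid oxidation had 1, 2 and 18 (median 0.04, adjusted p = 0.847), and glycolysis 2, 1 and 16 (median 0.04, adjusted p = 0.832). Polycomb genes had 2, 2 and 18, with 1 negative adjusted over the list alone (median 0.03, adjusted p = 0.886), and Hox genes 1, 1 and 3 (median −0.11, adjusted p = 0.832). MHC class II genes (median 0.03, adjusted p = 0.789) and stromal markers (median 0.10, adjusted p = 0.832) had no member called. Of the other markers, neutrophil genes had 1 of 7 positive (median −0.05, mean −0.04, camera direction up, adjusted p = 0.945), lymphocyte genes 1 of 5 (median 0.31, adjusted p = 0.692) and dendritic cell genes 2 of 6 (median 0.09, mean −0.18, camera direction up, adjusted p = 0.832).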

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

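The results here differ by genotype in the RANKL response, by the test of that difference in the fit of all libraries. Each response is a ratio to the macrophage level, which itself differed by genotype for many genes. A positive or negative difference therefore does not say which genotype had the higher level in osteoclast cultures. Tests chosen only after the result was seen are the splits of the libraries, the spread between libraries, the comparison of other cell types, the interval of the odds ratio and the share of induced genes at or above the flox level.

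The response differed for 2850 genes. Lists that differed, by the median of KO minus flox responses on the log2 scale, were macrophage genes (0.37), interferon response genes (0.34), cholesterol synthesis genes (0.15), osteoclast genes (−0.09), oxidative phosphorylation genes (−0.14), p53 targets (−0.36) and cell cycle genes (−0.41). With an estimated correlation the difference held for macrophage genes (camera adjusted p = 0.00246) and p53 targets (0.00804). It was lost for cell cycle (adjusted p = 0.0637), osteoclast (0.064), oxidative phosphorylation (0.149), interferon and cholesterol synthesis genes (each 0.24). Of the 148 genes named in the comparisons, 91 differed, where 21.9% of all genes tested did. The naming rule picks some genes by this same difference, which raises that count. Osteoclast and signalling genes with a lower response in KO cells were Jdp2 (−1.62), Acp5 (−1.19), Nfatc1 (−1.05), Prdm1 (−1.04), Rcan1 (−0.84), Tfec (−0.79), Atp6v0d2 (−0.31) and Clcn7 (−0.20), while Relb (0.85), Nfkb2 (0.45), Tnfrsf11a (0.37), Ckb (0.22) and Nfkbia (0.13) had a higher one. Macrophage genes with a higher difference were Cx3cr1 (1.37), Maf (1.05), Mertk (0.79), Cd14 (0.65), Ccr2 (0.62), C1qa (0.47), Adgre1 (0.37) and C1qc (0.34), against Axl (−0.49) and Mrc1 (−0.44).

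Cell cycle and p53 genes with lower differences were Ube2c (−0.66), Mdm2 (−0.63), Cdkn1a (−0.57), Ccna2 (−0.52), Aen (−0.44), Cdc20 (−0.43) and Plk1 (−0.41). Respiratory and glycolytic genes were Cyc1 and Cox8a (each −0.21), Atp5b (−0.19), Atp5a1 (−0.16) and Ldha (−0.15). Interferon and inflammatory genes were Cxcl10 (1.17), Ifih1 (0.45), Rsad2 (0.43), Ddx58 (0.34), Stat2 (0.26) and Socs3 (−1.15). Genes of lipid and sterol metabolism were Pparg (0.81), Cyp51 (0.40), Lipa (0.38), Nr1h3 (0.36), Hmgcs1 (0.23), Lpl (0.22), Gpnmb (−0.18) and Apoe (−0.23). Secreted factor, chromatin and early response genes were Spp1 (0.95), Metrnl (0.61), Pdgfb (0.36), Igf1 (0.32), Atf3 (0.31), Grn (0.21), Jarid2 and Tgm2 (each 0.19) and Junb (0.18).

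Other genes with a positive difference were Tmem26 (1.97), Ch25h (1.90), Bcar1 (1.88), Cav1 (1.86), Tmem176b (1.78), Lrrc4 (1.52), Zfp618 (1.47), Nt5e (1.44), Tnip3 (1.4), Itga8 (1.29), Ang (1.20), Lyl1 (1.13), Rnase4 (1.03), Spint1 (0.77), Tspan13 (0.71), Hpgd (0.68), Cd300lf and Fcrls (each 0.65), Cbr2 (0.54), Cd33 (0.48), Tspan32 (0.37), Lyz2 (0.29), Lyz1 (0.23), Ddx3y (0.22) and Marco (0.13). Negative ones were Plxna4 (−2.40), St14 (−1.79), Oaf (−1.21), Acy1 and Ccr1 (each −1.20), Bbs9 (−1.15), Mdm1 (−1.11) and Tln2 (−0.75).

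Other splits of the libraries bear on these counts. For the difference between responses, 2 of 60 splits, the real one included, called at least 2850 genes. The other of these exchanges both osteoclast groups, so that it tests the sum of the genotype effects, and it called 6328. The next highest called 1654, and 47 of the other splits called no gene by edgeR after adjustment, with 112 to 307 genes at an unadjusted p under 0.05. These other 58 splits mix flox and KO libraries within a group, so that genotype effects add to the spread, and the 2 splits that keep the genotypes apart are too few for a share under 0.05. For the pairwise comparisons 10 splits are also too few. Only the real split (1 of 10) reached 5203 genes for genotype in macrophages, 5381 in osteoclast cultures, 9747 for RANKL in flox cells and 9182 in KO cells. Every other split called 0 by edgeR after adjustment, and at most 612, 360, 301 and 195 genes at an unadjusted p under 0.05. These splits also mix the groups compared, so that their difference adds to the spread and low counts were likely in advance.

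Acp5, Jdp2 and Nfatc1 were induced less in KO cells, and a smaller share of responding cells could lower all induced genes alike. Among 231 genes with a mean log2 response of at least 2, 26.4% were at or above the flox level in KO osteoclast cultures, whether or not called. By the edgeR test 133 were lower and 29 higher, and the 29 argue against that share as the only cause. The 231 genes were already lower in KO macrophages (median −0.62), so their level in osteoclast cultures does not isolate the share of responding cells. For the 26.4% the bound was 20%. It was set after a first version on responses (61.5% at or above flox) was found to measure a ratio to baseline, and the margin is small. Fgr (143 to 216 CPM), C3 (113 to 201 CPM) and Zbtb32 (28.3 to 38.7 CPM), picked after their values were seen, were higher in KO cells. A smaller share together with gene-specific changes stays open, as does an effect of ASXL2 itself or of Cre, neither of which was tested apart from genotype.

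Stromal genes were lower in KO cultures in both cell states. Fewer stromal cells would lower other stromal genes alike, and all 23 of 29 further genes that reached 1 CPM were lower in both, with a median of −1.49 (quartiles −1.63 and −1.32) in macrophage cultures against −1.64 (quartiles −1.82 and −1.52) for the list. Abundant members were Col1a1 (91.4 to 28.6 CPM in macrophage cultures), Col1a2 (69.0 to 21.3 CPM) and Acta2 (66.6 to 26.8 CPM), and no list member is in another list. Fewer cells of every other type cannot be told apart from this by neutrophil, lymphocyte and dendritic markers (medians −0.94, −0.69 and −0.07), since only 5 of 7, 3 of 5 and 1 of 6 lay between 1 and 100 CPM in flox macrophages. A carry-over of fewer stromal cells is a candidate explanation, and lower expression within these cells stays open.

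Many genes differed slightly by genotype, often in both cell states. Length bias is argued against by a Spearman correlation with gene length of −0.066 in macrophages and 0.079 in osteoclast cultures. Among the 608 genes with a shared change of at least 1.5-fold, DNA of another strain near Lyz2 stays open at an odds ratio of 1.24 (95% interval 0.328 to 3.35, 4 of 70 genes within 10 Mb, one-sided Fisher p = 0.413). For strain DNA elsewhere, 305 pairs of the 608 genes lay within 1 Mb (random draws 277 to 364, permutation p = 0.7). The genes as a whole did not cluster, but a few segments would add too few pairs to be seen, so this stays open too. Smaller shared differences were not part of these tests. Libraries of a group may share a culture or animal: their spread of 2.54% is low, the labels do not say, and this cannot be told apart from an effect of the deletion.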

How the results depend on the processing

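No test in this part was chosen after the results were seen. The genotype, RANKL and response-difference counts, their overlap and the Asxl2 fold changes kept their direction and stayed within 1.5 times under every alternative run except a 2-fold minimum. With it, genotype counts were 548 in macrophages and 550 in osteoclast cultures, RANKL counts 2267 in flox and 1811 in KO cells, the difference between responses 138 and the overlap 319, because most called differences were under 2-fold. With DESeq2 the counts were 4080, 4174, 8993, 8308, 2072 and 2166. Of 53 list calls 12 were made with an estimated correlation, while fry, which tests another hypothesis, called 86 directionally and 105 in either direction. Inflammatory genes turned from down to up with fry for RANKL (signed −log10 p 2.195 in flox and 5.37 in KO cells), and the cause was not tested.

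Leaving out 1 library at a time gave 4514 to 5190 genes for genotype in macrophages, 4703 to 5749 in osteoclast cultures, 9374 to 9810 for RANKL in flox cells, and 8745 to 9368 in KO cells. It gave 2447 to 3289 for the difference between responses, 2580 to 2916 for the overlap, 50 to 57 for lists, and log2 fold changes of Asxl2 of −2.65 to −2.601 and −2.492 to −2.365. No named gene lost its call under an alternative that gave it a value, and the 2-fold minimum was applied to counts and the overlap only. Among single list results, 13 lost and 8 gained a call without 1 library, 42 lost and 31 gained one under another setting, and 4 lost one with the replicate block.

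Same-numbered libraries did not deviate together (correlations −0.035 to 0.04 over 18 pairs, and 3 of 12 libraries correlated best with their own number). This shows no pairing by number, but at a spread of 2.54% between libraries of a group a pairing could go unseen. With the number as a block the counts were 5150, 5333, 9728, 9153, 2783 and 2806, and 49 list calls. With a block within genotype they were 9684 and 9106 for RANKL and 2719 for the difference between responses. Depth limits what can be said of genes with few counts.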

Other observations

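The test of chromosome 9 was chosen after the result was seen, and the genes named in this part were picked after their values were seen.

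Catecholamine handling, of interest in work on energy expenditure, could not be tested as a list. Maoa, which encodes a monoamine oxidase, rose in KO cells from 16.39 to 22.87 CPM in macrophages (log2 fold change 0.48, edgeR adjusted p = 2.16e-07) and from 22.28 to 30.36 CPM in osteoclast cultures (0.45, edgeR adjusted p = 3.86e-08). Th, Dbh, Slc6a2 and Adrb3 had no count in any library, which allows up to 3 counts in each.

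Transcripts of the 14 tested mitochondrially encoded genes took 0.995 ± 0.13% of counts in flox macrophages, 0.834 ± 0.067% in KO macrophages, 1.01 ± 0.035% in flox osteoclast cultures and 1.19 ± 0.12% in KO osteoclast cultures (SD, n = 3). Their median difference between RANKL responses was 0.56 on the log2 scale, with 7 of 14 called higher. The median stayed between 0.45 and 0.60 under every alternative that kept these genes. The count of calls was 2 without flox or KO osteoclast library 2 or 3, flox macrophage library 2 or 3 or KO macrophage library 1 or 3, 4 without flox osteoclast library 1, 2 without a filter, 8 with DESeq2 and 9 with limma-voom or without flox macrophage library 1. The median was opposite in sign to the nuclear-encoded oxidative phosphorylation genes (−0.14).

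Mdm2, Rap1b and Mdm1 lie 412, 537 and 864 kb from Lyz2, which carries the Cre insertion, and had lower RANKL responses in KO cells (−0.63, −0.47 and −1.11 on the log2 scale). They were picked from 70 tested genes within 10 Mb of Lyz2. Lyz2 itself (0.29) and the neighbouring Lyz1 (0.23) had differences of the opposite sign. Whether the insertion affects any of these genes was not tested.

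Of the 34 genes whose RANKL response was at least 2-fold lower in KO cells, 8 lie on chromosome 9, which holds 5.5% of tested genes: Acp5, Bbs9, St14, Oaf, Rpl10-ps3, Gm3671, Acy1 and Ccr1. The one-sided Fisher p adjusted over 20 chromosomes was 0.0081, but the chromosome, the direction and the 2-fold limit were picked from the same data, so that this p only describes these genes. Of the 8, Rpl10-ps3 is a pseudogene and Gm3671 a gene model.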
